A study of Mus musculus with 16 samples.

How the data were processed

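Genomic DNA of 16 cultured mouse tumour lines was hybridised to 2-colour comparative genomic hybridisation arrays, with 1 array per line. Per the labels, the DNA of the line carried the red dye Cy5 and a commercial mouse genomic DNA, the same on every array, carried the green dye Cy3. The log ratio of red over green is therefore the line over the reference, and a positive value is a relative gain.

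The spot intensity values were made with Agilent Feature Extraction, named in the submitters' processing notes; its version was 10.7.3.1 per the file headers. The processed intensity values were background-subtracted, detrended and scaled between dyes with a linear factor, and no lowess curve was applied, per the file headers. The deposited log10 ratio of each spot equalled the ratio of its processed signals to within 0.001 in log2 for at least 99.9% of spots on every array. The deposited value table of the series is in log2 units: it differed from that ratio, taken to log2, by at most 5.06e-05, so its scale, direction and lack of further centring were settled from the files. Its column medians ran from -0.044 to 0.053. Flags for outlier spots and for signal above background came with the deposited files and have no unit other than 0 or 1. Probe positions were on the mouse build mm8, per the file headers.

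The main values were log2 of the processed red over the processed green signal, with outlier-flagged spots and control spots left out and repeat spots of a probe averaged. Each array was centred on the median of its autosomal probes, without loess or quantile normalization. Of 235402 probes, 1940 had no position and 248 lay on unplaced sequence. The 233212 probes used comprised 220668 autosomal, 11951 X and 593 Y probes, at a median spacing of 7827 bp.

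Each profile was divided into segments by an exact change point search with a squared-error cost. The penalty was 6 times the squared noise times the log of the number of autosomal probes, and a segment held at least 5 probes. Before the search, a probe was limited to within 3 noise SDs of the running median of 5 probes. A segment mean at or above 0.3 was a gain, and one at or below -0.3 was a loss. A focal segment was shorter than 5 Mb, and a whole-chromosome change covered at least 90% of the probes of a chromosome. Where a probe was not well above background in a channel, its signal was replaced by the higher of its own value and the lowest signal among probes well above background on that array, and the resulting fold is given as "at least". The error of a segment is the SE over its probes, which measures noise along the genome and not the spread between cultures.

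The lines fall into 12 families, since 4 arrays carry B16 sublines and 2 carry TRAMPC sublines. Recurrence was tested by shifting each family's profile of 1 Mb bins in a circle along the autosomes in 10000 seeded draws, with the highest count per draw giving a one-sided family-wise p. Probes of the 3 Balb/C lines were compared with those of 8 C57BI6 families by limma (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05, on autosomal probes with a value in every family. P815, the only DBA/2 line, stayed out of that fit. B16F0 was compared with B16F10 by limma on means of 1 Mb bins. Other comparisons had 1 array per side and no test. Families and lines are the only replicates. The limma p-values of the strain comparison measure the spread between lines, and those of B16 the spread between the 2 arrays of each subline. The permutation p-values compare positions along the genome, or chromosomes for the gene lists, and do not measure the spread between lines.

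The files fall into 2 scan batches, of 6 and 10 arrays. All 3 Balb/C lines were in the first, with Hepa1-6, ID8 and B16F10 NCI. The strain fit was therefore repeated with the scan batch as a block and within the first batch.

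The rule for named items, fixed before the data were examined, took the highest and the lowest focal segment of each line if at or past 1 in size, and the strain differences of largest size in each direction. The files pair no probe with a gene, and the gene table used here is on the build GRCm38, so its positions were not used. The rule was therefore applied to positions: for the strain comparison it took runs of at least 2 neighbouring probes called in the same direction. The parts of the rule that name list genes, antigen receptor loci and single tumour genes, and the planned gene list test, were not run. In their place, a test chosen after seeing the data used only the chromosome of each list gene: 232 genes of 8 lists were placed through the symbols and synonyms of the gene table, and the mean chromosome value of a list was compared with 10000 permutations of the 19 autosomes within each family.

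The segmentation was tested on simulated profiles. At the median noise of the arrays, 40 of 40 planted segments of 1000 probes at 0.3 and 40 of 40 of 5 probes at -3 were recovered, against 0 of 40 segments of 10 probes at 1 and 34 of 40 of 20 probes at 1. At the highest noise, 8 of 40 segments of 20 probes at 1 were recovered, and a profile with no change gave 0 false gains or losses at either noise. Numbers of focal segments are therefore not compared between lines. In simulated data for the strain comparison on 220255 probes, limma recovered 58 of 100 planted differences of 1 and 97 of 100 of 2 in log2, with 5 false calls. In 100 simulated sets of shifted profiles, the recurrence test made a gain call in 0 and a loss call in 3. These sets were made by the same shifts as the test itself, with fewer draws. They check its working, and not how it behaves where all arrays share a component.

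Alternatives were normexp background correction in limma, the deposited value table, mode centring, removal of 1465 probes that were dim in the reference on any array, other thresholds, penalties, segment and bin sizes, other ways of counting sublines, and leaving out each family. The correlation for the fit with the family as a random block was estimated on a seeded subset of probes. Normexp used median spot signals in place of the planned mean signals, which were not used here. It added a constant to each signal and was followed by median centring only, without the detrending of the processed signals. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.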

Results

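The series profiled DNA copy number in 16 syngeneic mouse tumour lines, which are lines that can be grown in immunocompetent mice of their own strain, as part of a wider description of models for immunotherapy research. The tumours include colon (CT26, MC38), lung (LL2), breast (4T1), melanoma (4 B16 arrays), mastocytoma (P815), liver (Hepa1-6), pancreas (PAN02), prostate (TRAMPC1, TRAMPC2), lymphoma (EL4), ovary (ID8) and kidney (Renca). Per the labels, 3 lines are Balb/C, 1 is DBA/2 and 12 are C57BI6. Each line had 1 array and no replicate, and the number of arrays limits the precision. The line channel was well above background for 99.2% to 99.9% of probes, and the noise between neighbouring probes ran from 0.22 to 0.41 in log2, with a median of 0.34.

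The first comparison asked how much of each genome was altered. Renca, the kidney line, was the most altered, with 8.13% of the autosomes gained and 31.5% lost. It lost nearly all of chromosome 13 (median log2 ratio -0.39) and chromosome 9 (-0.36) and gained chromosome 16 (0.52). The lowest shares were 12.6% in LL2 and 12.8% in Hepa1-6, and the median over the 16 arrays was 20.7%. PAN02, whose profile was nearly the same as that of Hepa1-6, stood at 21.1%, since segments near the cut of 0.3 fell on either side of it. Chromosome 19 was gained over 0% of its probes in Hepa1-6 and 100% in PAN02, at medians of 0.26 and 0.28. The low rank of Hepa1-6 therefore depends on the cut. ID8, the ovarian line, gained chromosomes 15 (0.64) and 19 (0.70) along their whole length. TRAMPC1 and TRAMPC2 both lost chromosome 7 (-0.58 and -0.57), and all 4 B16 arrays gained chromosome 6 (0.62 to 0.77). EL4 showed few gains (3.38%) but large blocks of stronger loss, such as 33.2 Mb of chromosome 3 at -0.92 ± 0.0060 (SE, 2430 probes) and 25.7 Mb of chromosome 13 at -0.87 ± 0.0058 (SE, 2389 probes). P815 likewise lost 28.0 Mb of chromosome 10 at -0.94 ± 0.0093 (SE, 2250 probes). The share depended on centring and threshold: with mode centring CT26 was the most altered at 46.8%, and the median over arrays was 39.2% at a threshold of 0.2, 7.04% at 0.5 and 11.4% with normexp background correction. The least altered line was P815 with mode centring (16.9%), Hepa1-6 with the penalty doubled (7.94%) and B16F0 ECAC with normexp (0.484%).

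**Figure D1:**
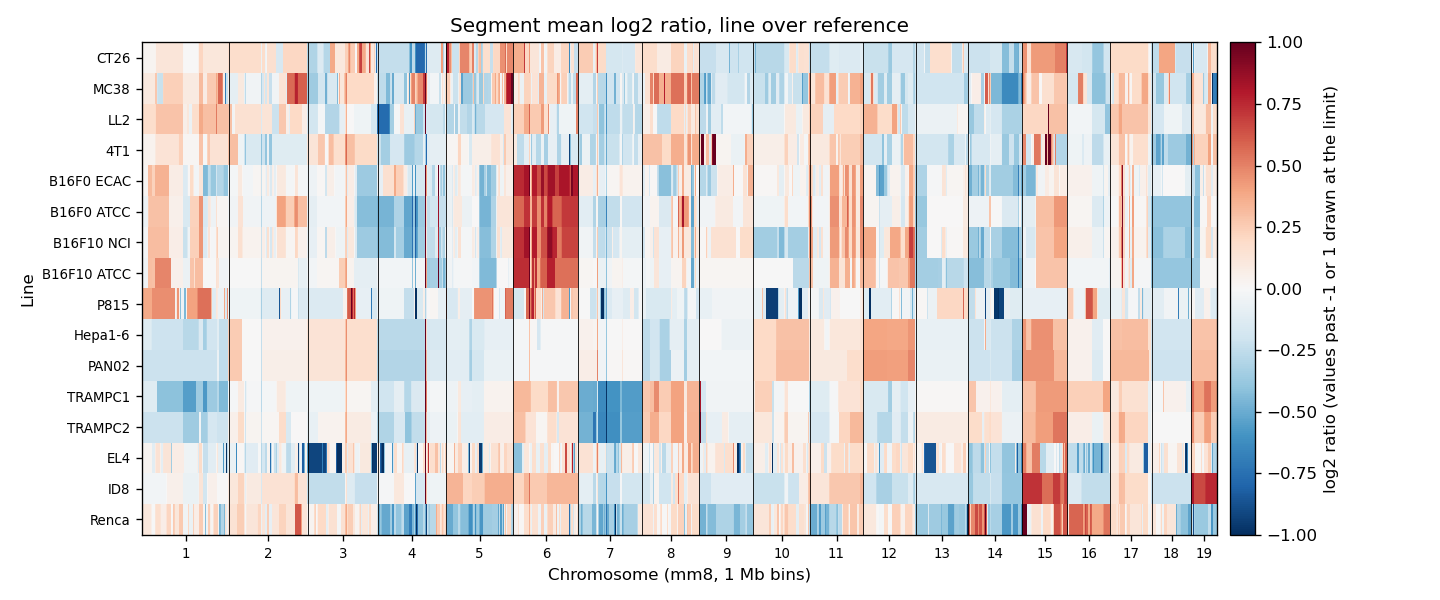
Segment mean log2 ratio of line over reference in 1 Mb bins (x axis, chromosomes 1 to 19 on mm8) for the 16 arrays (y axis), with red for gain and blue for loss and values past -1 or 1 drawn at the limit. Chromosome 6 is red in all 4 B16 arrays (0.62 to 0.77), and chromosome 7 is blue in both TRAMPC arrays.

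Several lines carried amplified or deleted segments under 5 Mb. LL2, the lung line, had its highest segment on chromosome 15 from 61440614 to 62200089 (mm8), at 4.00 ± 0.056 in log2 (SE, 65 probes), which is a 15.98-fold ratio. In 4T1, the breast line, a segment of the same chromosome from 61254105 to 61460967, which overlaps the start of that in LL2, stood at 2.59 ± 0.11 (SE, 13 probes). 4T1 also had 2 long high segments on chromosome 9, of 5.21 Mb at 1.34 and 7.08 Mb at 1.25. In 11 C57BI6 arrays the highest focal segment lay within chromosome 4 from 111579573 to 112104237, where most probes were not well above background in the reference, so that the ratios there are bounds and their rank is not exact. From 111579573 to 112091131 the mean was past 1 in all 8 C57BI6 families, and in no Balb/C line nor in P815. This segment thus follows the strain label and is not particular to any tumour. The lowest focal segment lay on the X chromosome in 5 of the 6 B16 and TRAMPC arrays, such as 83723484 to 83851355 in B16F0 ECAC (at least 19.4-fold lower than the reference) and 83691789 to 83806830 in TRAMPC1 (at least 18.6-fold lower). Most probes of these segments were not well above background in the line, so their rank as lowest is not exact either. Segments found in 1 family, where no other reached 0.5 in the same direction, were picked after their values were seen. P815 gained chromosome 3 from 101048565 to 104256971 at 1.24 (360 probes). Deletions of this kind included chromosome 6 from 62061489 to 62258209 in CT26 (at least 10.5-fold lower than the reference) and chromosome 18 from 80761850 to 80811566 in EL4 (at least 12.5-fold lower). The lowest focal segment of EL4 by its ratios was on chromosome 14 from 114617754 to 114640676, at least 18.7-fold lower. Its 6 probes were all not well above background in the line, so its rank is not exact. With normexp, the deletions named by the fixed rule were shallower: -0.23 in B16F0 ECAC, which is no longer a loss, -1.93 in TRAMPC1 and -0.94 in EL4, while the LL2 gain was 4.10 and that of 4T1 3.03. Normexp flattened the B16F0 ECAC array as a whole: its altered share went from 27.5% to 0.484%. Its highest focal segment went from 4.46 to 0.088. The -0.23 is therefore no measure of copy number alone and does not decide whether that deletion is present.

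A deletion on chromosome 4 was shared by tumours of different tissues. In the part common to the most families, from 88748620 to 88759744 (3 probes), the line signal was not well above background in CT26, MC38, LL2, 4T1, P815, ID8 and all 4 B16 arrays, at least 19.5-fold below the reference in each. Renca stood at -1.41 ± 0.079 (SE, 3 probes), above the floor. TRAMPC1, TRAMPC2, Hepa1-6 and PAN02 lay between -0.45 and -0.64, and EL4 lay at -0.053. The region also held the lowest focal segment of MC38, LL2, B16F0 ATCC and ID8 by the fixed rule. Most probes of those segments were not well above background in the line, so their rank as lowest is not exact. The 3-probe part was chosen after its values were seen. With normexp the lowest focal segments of MC38, LL2, B16F0 ATCC and ID8 stood at -2.02, -1.16, -1.48 and -0.42. Genes in these segments were not identified, since gene positions on mm8 were not used here.

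**Figure D2:**
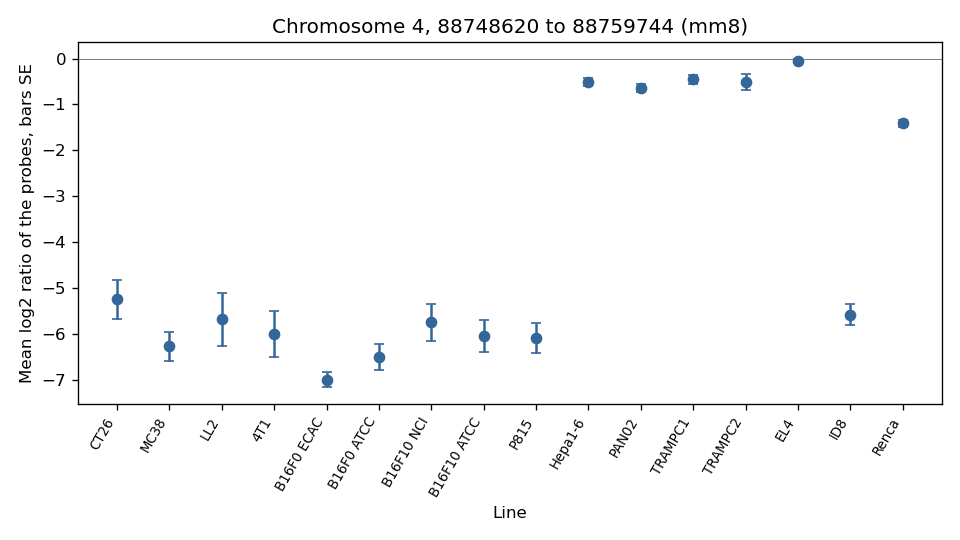
Mean log2 ratio (y axis) of the 3 probes on chromosome 4 from 88748620 to 88759744 on mm8 for each of the 16 arrays (x axis), with bars for the SE over probes. 10 arrays, whose line signal was not well above background and whose exact level is therefore unknown, lie between -5.25 and -7.00, Renca lies at -1.41, and the other 5 lie between -0.64 and -0.053.

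Recurrence over the 12 families was examined in 2408 bins of 1 Mb. Each family was shifted independently, so a component that all arrays share through the common reference would also pass. The test cannot separate such a component from recurrent change in tumours. Pairs of different families correlated at a median of 0.27 across bins. That median was -0.038 after the median over families was subtracted, a step that would remove either. Gains passed the permutation test in 14 bins, of which 10 formed 1 region at the start of chromosome 15 (3 to 13 Mb), gained in 9 of 12 families with a mean of 0.42 ± 0.36 (SD, n = 12; one-sided family-wise permutation p = 0.00040). The chromosome 15 median was above 0 in 11 of 12 families. Losses passed in 40 bins: 38 on the distal part of chromosome 14, in 7 to 10 families (79 to 95 Mb with a mean of -0.36 ± 0.15, and 102 to 124 Mb with -0.34 ± 0.14, SD, n = 12; one-sided family-wise permutation p = 0.00020 and 1e-04, the latter the smallest the draws can give), and 2 on chromosome 7 (67 to 69 Mb, mean -0.52 ± 0.19, SD, n = 12), in 10 to 12 families (one-sided family-wise permutation p = 1e-04, again the smallest). The chromosome 7 loss is not specific to any line: from 67535802 to 68232063 (79 probes) each of the 16 arrays was low, between -0.54 and -1.36. The 3 single bins on chromosomes 4 and 8 that passed as gains, at 111, 121 and 22 Mb, were gained in the 8 C57BI6 families alone (one-sided family-wise permutation p = 0.0056). The Balb/C lines and P815 stayed below 0.3 in each, so these bins divide the families by the strain label. A difference between strain and reference would pass this test too, so the p-value does not show recurrent change in tumours there. With normexp 0 of the 3 passed. Neither on chromosome 4 passed with mode centring or at a threshold of 0.2, and that on chromosome 8 failed with the penalty doubled. Without shared probe effects 0 of the 3 passed, but that setting subtracts from each probe the median over families, taken against its local level. It removes a short gain present in most families by design, so this failure is no evidence about these bins. The bin at 111 Mb also failed without probes dim in the reference. With mode centring, 0 of the 10 bins at 3 to 13 Mb of chromosome 15 passed, while 9 others between 78 and 104 Mb did, and 6 of the 38 bins on chromosome 14 passed. With normexp the 10 bins of chromosome 15 passed and 0 on chromosome 14, and at a threshold of 0.5 no bin of either region passed.

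By chromosome, the genes of 8 lists fixed beforehand were set against permuted chromosomes, a test chosen after seeing the data. The interferon signalling list was lower than permuted chromosomes (mean -0.073 over 32 genes, two-sided permutation p = 1e-04, the smallest the draws can give, adjusted p = 0.00080 over 8 lists). 12 of its genes lie on chromosome 4, whose mean was -0.15, and its other genes had a mean of -0.024. The antigen presentation list was higher (mean 0.098 over 22 genes, permutation p = 0.0019, adjusted p = 0.0076); 10 of its genes lie on chromosome 17, at a mean of 0.17, and the others had a mean of 0.038. The chemokine and cytokine (adjusted p = 0.13), tumour suppressor (0.30), oncogene (0.39), DNA repair (0.42), melanocyte lineage (0.56) and checkpoint ligand (0.85) lists did not pass. These values describe chromosomes, not the genes themselves. The chromosome 4 median was below 0 in 11 of 12 families, and that of chromosome 17 was above 0 in 11 of 12. Chromosomes were permuted within each family, so a component that all arrays share through the common reference would also give a small p. This test too cannot separate such a component from recurrent change in tumours.

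The strain comparison set 3 Balb/C lines against 8 C57BI6 families, all measured against the same reference. Of 220255 autosomal probes, 5153 differed (limma, adjusted p under 0.05), 4359 lower and 794 higher in Balb/C. The 10 runs of neighbouring probes with the largest differences were at least 6.92-fold to 16.1-fold lower in Balb/C, and the 10 largest in the other direction were 2.40-fold to 3.96-fold higher. Chromosome 19 from 9253858 to 9299188 stood at -5.22 ± 0.49 (SD, n = 3) in Balb/C against 0.37 ± 0.30 (SD, n = 8), at least 16.1-fold lower (largest adjusted p = 8.3e-09), and P815 lay at 0.12. Chromosome 6 from 132609315 to 132622717 was at least 16.02-fold lower in Balb/C, and P815 shared the loss at -5.71. Chromosome 11 from 70987724 to 71109796 (11 probes) was -3.66 ± 0.052 (SD, n = 3) in Balb/C against 1.03 ± 0.073 (SD, n = 8), at least 14.04-fold lower, with P815 at -2.75. On chromosome 4 the 13 probes from 111724836 to 111862804 were at least 9.20-fold lower in Balb/C lines than in C57BI6 families; the line signal of Balb/C, and the reference signal at most probes of the locus, were not well above background, so no exact level is given. The Balb/C means at the lower runs on chromosomes 19, 6 and 11 also rest wholly or mostly on such probes, and the bound, not the mean, is the measured difference. In the other direction, chromosome 7 from 37887916 to 37909600 was -2.14 ± 0.25 (SD, n = 8) in C57BI6 and -0.15 ± 0.34 (SD, n = 3) in Balb/C, 3.96-fold higher in Balb/C. Chromosome 1 from 173348489 to 173405431 was 3.92-fold higher in Balb/C. All Balb/C lines were in 1 scan batch: with the batch as a block limma called 2379 probes, of which 2356 were shared with the fit without it, and within that batch (3 against 3) it called 3180, of which 3001 were shared. With normexp it called 1291, of which 30.4% were higher in Balb/C, against 15.4%.

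Sublines of the same tumour were compared next. TRAMPC1 and TRAMPC2 differed in 1.53% of the autosomes. The longest difference was 31.9 Mb of chromosome 16, at 0.31 ± 0.0088 in TRAMPC1 and -0.014 ± 0.0096 in TRAMPC2 (SE over 2356 probes). A gain on chromosome 9 from 4948530 to 8306675 was present in both and higher in TRAMPC2 (1.44 ± 0.024 against 0.82 ± 0.020, SE over 288 probes). Without replicates, these differences compare single arrays, and the share was 25.2% with normexp. Normexp did not act alike on the 2 arrays: under it the altered share was 31.9% in TRAMPC1 and 0.61% in TRAMPC2.

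B16F10, a subline of the melanoma line B16F0, was compared with it using 2 arrays each. No 1 Mb bin differed after adjustment (limma, 0 of 2408 bins, lowest adjusted p = 0.51), and 120 bins had an unadjusted p under 0.05. The bin with the largest difference, chromosome 12 from 98000001 to 99000000, was 0.40 in B16F10 and -0.0029 in B16F0 on average (difference 0.40 ± 0.082 (SE, n = 2 against 2), adjusted p = 0.51). Of the 10 bins with the largest differences, 8 lay on chromosome 12, each higher in B16F10, by 0.35 to 0.40. The chromosome 12 median, singled out after its values were seen and not tested, was 0.31 and 0.25 in the 2 B16F10 arrays and -0.030 and 0.014 in the 2 B16F0 arrays, a difference of 0.29 that was 0.17 with normexp. Both B16F0 arrays and B16F10 ATCC were in the second scan batch; within it, with B16F10 NCI left out, 0 bins passed and 155 had an unadjusted p under 0.05. The arrays of 1 subline from different suppliers also differed: chromosome 18 was lost in B16F0 ATCC (-0.42) and not in B16F0 ECAC (-0.040), and chromosome 14 stood at -0.37 in B16F0 ECAC and -0.079 in B16F0 ATCC. In all, 24.0% of the autosomes differed between the 2 B16F0 arrays and 9.98% between the 2 B16F10 arrays.

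Across 1 Mb bins, the 7 pairs of sublines correlated at 0.73 to 0.92, with a median of 0.77, against -0.12 to 0.51 (median 0.27) over 112 pairs from different families. The arrays labelled Hepa1-6 (liver) and PAN02 (pancreas) correlated at 0.99, above each pair of sublines, and 0.083% of their bins differed by 0.3 or more, against 19.4% to 48.6% for other pairs of different families. With normexp the correlation was 0.90, and the share of the autosomes in segments that differed went from 0.079% to 7.37%. Both carried gains over most of chromosomes 12, 15 and 17, and both had their lowest focal segment at the same place, chromosome 12 from 57870667 to 57898258. On each array 4 of its 5 probes were not well above background in the line, so its rank as lowest is not exact. Values for these arrays are given under their labels; counted as 1 family, they left 15 gained and 35 lost recurrent bins and 4813 strain probes. Bins are not independent replicates.

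**Figure D3:**
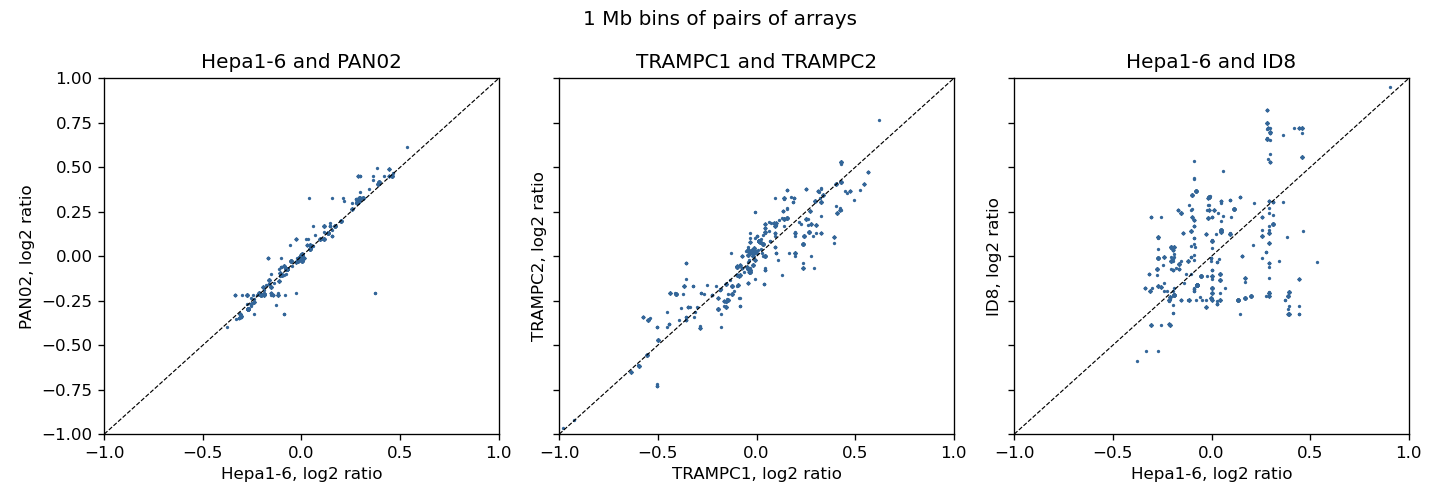
Log2 ratios of 1 Mb bins (points) of pairs of arrays, with 1 array on each axis and a dashed line of equality; bins past -1 or 1 lie outside the range drawn. The points of Hepa1-6 and PAN02 follow the line (r = 0.99), as do most of those of TRAMPC1 and TRAMPC2 (r = 0.92), while Hepa1-6 and ID8 scatter widely (r = 0.33).

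On the sex chromosomes, the 2 lines labelled male, TRAMPC1 and TRAMPC2, had median Y log2 ratios of 3.13 and 3.14, at least 5.70-fold and 5.88-fold above the reference, where the reference was well above background for 47.2% and 47.6% of Y probes. The 14 lines labelled female lay between -0.999 and -0.55, and their own signal was well above background for 24.1% to 40.6% of Y probes. The X median of those 14 lines ran from -1.28 in B16F0 ATCC to -0.34 in ID8, with a median of -1.05, and the TRAMPC lines stood at -1.09 and -0.98. With normexp, the mean Y value of the male lines was 0.28 and the X median of the female lines -0.41.

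**Figure D4:**
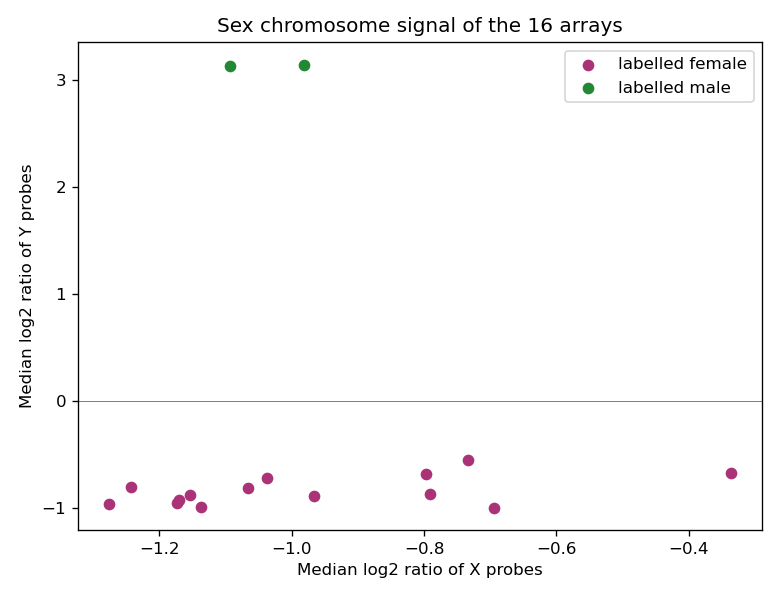
Median log2 ratio of X probes (x axis) and Y probes (y axis) of each of the 16 arrays (points), coloured by the sex in the labels. The 2 lines labelled male lie at 3.13 and 3.14 on the y axis and the 14 labelled female lie at -0.55 or lower.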

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

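The fit with the scan batch as a block, the correlation after subtracting the median over families, mode centring and the share of lower probes with no called neighbour were planned; their use as tests of an explanation, apart from that share, and the other tests in this part were chosen after the result was seen. Of 46 sets of lines examined, 8 had a member that stood apart by Dixon's ratio, where chance alone marks about 1 in 20. Among the 4 B16 arrays, B16F10 NCI had the highest share lost (22.9%, next 15.8%), and B16F10 ATCC the lowest chromosome 13 median (-0.32). B16F0 ATCC had the highest chromosome 14 median (-0.079), and B16F0 ECAC the lowest chromosome 15 median (-0.035) and the highest chromosome 18 median (-0.040). Among the 8 C57BI6 families, B16 was highest on chromosome 6 (0.68), and TRAMPC was lowest on chromosome 7 (-0.58) and highest on chromosome 14 (0.033).

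The arrays labelled Hepa1-6 and PAN02 had nearly identical profiles although their labels give different tissues. A component common to all arrays is argued against by the correlation of 0.98 that stayed after the median over families was subtracted, against at most 0.17 in 112 pairs of different families. Separate tumours with the same recurrent changes are argued against by the same value, which lay 8.63 SDs of those pairs above their mean. The same DNA or line on both arrays may be the source: 0.083% of bins differed, below the lowest value for sublines of 1 family (1.41%). With normexp the segmented difference rose from 0.079% to 7.37%, against 25.2% for the TRAMPC sublines. Normexp did not act alike on the arrays of a pair. It took the altered share from 12.8% to 22.5% in Hepa1-6 and from 21.1% to 0.49% in PAN02. The share went from 24.0% to 31.9% in TRAMPC1 and from 20.3% to 0.61% in TRAMPC2. The differences with normexp are therefore no measure of copy number alone and do not decide the question. Which label is right, and whether this arose in the DNA or in the culture, is not shown by these arrays.

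Most lines labelled female had an X log ratio near -1. A reference with 1 X chromosome is argued against by the lines labelled male, whose X median was -1.04 where such a reference would give about 0. Centring is argued against by its largest effect on an array, 0.22. Loss of an X copy in culture, or an origin other than the label says, may remain; neither was tested.

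More probes were lower than higher in Balb/C lines. Of 100 splits of the 11 families, 1, the real one, gave as many calls in both directions together (5153), and the highest other gave 18. At 1 in 100 of the splits run, this argues against chance for the number of calls but does not exclude it. Other splits mix the strains, so a strain difference widens the spread within their groups and lowers their calls. The other splits made too few calls to test the balance of directions. The scan day as the whole cause is argued against by calls within 1 scan batch, where the number of lower probes was 63.0% of that in all arrays (2748 lower and 432 higher), although the fit with the batch as a block called fewer (2379), so a part may come from it. Strain variants under single probes stay open: of the probes called lower, 76.8% had no neighbouring probe called lower, but the share was 71.9% among those called higher, so it does not set the lower calls apart.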

How the results depend on the processing

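The alternatives with shared probe effects removed, with Hepa1-6 and PAN02 counted once, within scan batch 1 and the chromosome test of gene lists were chosen after seeing the data. The planned gene list tests and the calls of named genes were not run, for want of gene positions on mm8. No paired analysis was possible because each line had 1 array. The deposited value table left each compared result within its limit. Noise along the genome and the number of lines limited the precision, though their weight against other limits was not tested. Segments of 10 probes at 1 in log2 were beyond the search. The normexp setting mattered too: with it the altered share moved in each of the 16 lines. It also used median spot signals, added a constant and left out the detrending, so the moves cannot be assigned to background correction alone. Probes dim in the reference limited the high focal segments and the Y values: without them 13 of 32 named focal segments moved, such as the highest of MC38 from 5.55 to 3.20 and of P815 from 2.14 to 0.81. Except where a value shows it, the cause was not tested.

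The median altered share of 20.7% moved to 11.4% with normexp, 28.1% with mode centring, 21.7% without dim reference probes, 18.5% with the penalty doubled, 20.5% with at least 10 probes, 39.2% and 7.04% at thresholds of 0.2 and 0.5, and 24.1% without shared probe effects. The 14 recurrent gained bins became 38 with the penalty doubled, 91 and 4 at 0.2 and 0.5, 29 without shared probe effects, 43 with all 16 lines separate and 26 with 1 subline per family. With mode centring 13 gained bins passed, of which 2 were shared with the 14. The 40 lost bins became 2 with normexp, 10 with mode centring and 3 at 0.5; with Hepa1-6 and PAN02 counted once, 15 and 35 bins passed. The TRAMPC difference of 1.53% became 25.2% with normexp, 1.90% with mode centring and with the penalty doubled, 1.47% without dim probes, and 2.04% and 0.14% at 0.2 and 0.5. Its direction turned with normexp: 12.1% was higher and 13.1% lower in TRAMPC1, against 1.39% and 0.14%. Normexp took the altered share to 31.9% in TRAMPC1 and 0.61% in TRAMPC2, so this turn is not read as a change of copy number. The Hepa1-6 and PAN02 difference of 0.079% became 7.37% with normexp, nearly all higher in Hepa1-6 where the 0.079% was lower, and 0 with mode centring, without dim probes and at 0.5. With normexp the X median became -0.41 and the Y mean of the male lines 0.28; without dim probes the Y mean became 1.52.

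The 5153 strain probes became 1291 with normexp (30.4% of them higher in Balb/C, against 15.4%), 7948 with broad segments subtracted, 356 bins of 100 kb, 2379 with the scan batch as a block and 3180 within scan batch 1. Leaving out each family gave 3760 to 5343 calls. B16 bins stayed at 0 in each limma fit, with 22 to 450 of 2408 bins of 1 Mb and 992 of 23603 bins of 100 kb at an unadjusted p under 0.05, leaving out each array included, where the lone array is assumed to vary like the others; in the ATCC pair alone, 409 bins differed by 0.3 or more, against 65 for the means. Of the altered shares of single lines over all alternatives, 112 moved and 32 did not. A small change counted as a move: the share of LL2, 12.6% in the main analysis and 12.4% with at least 10 probes per segment, was among those that moved. Of 32 named focal segments, 31 moved with normexp, and some were no longer past 0.3 in size, such as the lowest of B16F0 ECAC (-0.23) and of PAN02 (-0.18). Normexp also took the altered share of these arrays to 0.484% and 0.49%, so the values do not decide whether the deletions are present. The correlation of Hepa1-6 and PAN02 was 0.90 with normexp.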

Other observations

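Some focal differences from the reference were common to all lines and so belong to no comparison of tumours. On chromosome 2 from 77680396 to 77792980 (12 probes) each of the 16 arrays was low, between -1.72 and -2.18. Each array was high, between 1.37 and 2.49, on chromosome 5 from 62046391 to 62093143 (5 probes), the highest focal segment of CT26 and P815. On chromosome 3 from 91238803 to 91307734 (5 probes) each was high, between 1.53 and 2.35, and this bin was among those that passed as recurrent gains, though not with normexp, without dim reference probes, with the penalty doubled, with at least 10 probes, at 0.5 or without shared probe effects. The last of these settings removes a short change common to most families by design. The loss on chromosome 7 from 67535802 to 68232063 is a further locus low in each of the 16 arrays. A further 20 loci were at or below -1 in the 3 Balb/C lines and in no C57BI6 family.

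Sharing of breakpoints did not identify related lines: 80.0% of breakpoints were shared, within 5 probes, by Hepa1-6 and PAN02, but 81.3% by Hepa1-6 and TRAMPC1, which are of different families and the same strain.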
